A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

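Total RNA of fission yeast (Schizosaccharomyces pombe) was sequenced in 4 libraries. Per the labels, all came from homothallic (h90) cells whose pcr1 gene was replaced by ura4+. Of these, 2 libraries carried the empty expression plasmid pREP41 and 2 carried pREP41 with Atf1. pREP41 drives its insert from a thiamine-repressible nmt1 promoter. Per the labels' protocols, cells grew at 30 °C overnight with 20 µM thiamine and then 24 h without it. RNA was taken with Trizol, and a stranded poly(A) mRNA kit was used for the libraries. The labels do not say whether the 2 libraries of a group came from separate cultures.

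The submitters' processing notes name HISAT2 and Cuffdiff, with no version, and the build ASM294v2. Per the file headers, the authors gave FPKM (fragments per kilobase of transcript and sequencing depth), with 1 pooled value per group and gene. The authors also deposited a p-value, a q-value and a log2 fold change per gene from their Cuffdiff comparison. Their log2 fold change is vector over Atf1, and it differed from the log2 ratio of the deposited FPKM by at most 4.81e-05. It is a spreadsheet error in 73 cells. The FPKM of both deposited tables were identical in all 7092 genes. The p-values have a floor of 5e-05, reached by 75 genes, and each of these has a q-value of 0.00809 in the authors' deposited table. Over how many tests the authors adjusted is not given in the sources used here. How the authors scaled the groups against each other is not given in the sources used here. The depth of the libraries is unknown, since the files hold no counts.

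The fits planned before the data were examined (limma on log2 values per library, camera on gene lists, leaving out libraries, and a replicate block) need values per library and were not run. No test was therefore computed here, and a statement that a gene rose or fell rests on the authors' q-value under 0.05. No SD or n can be given for any value, and the calls have no replicate check here. How Cuffdiff modelled the spread behind the p-values is not given in the sources used here. The p-values can rest on no more than 2 libraries per group, whose spread may be technical.

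Differences are log2(FPKM + 1), Atf1-labelled minus vector-labelled, a scale that understates changes of genes with low values. Genes with status OK in the authors' deposited table and a mean of at least 1 FPKM over both groups were kept, which left 6219 genes, of which 5011 are nuclear protein-coding. In the table, 6452 genes have status OK, 628 were not tested and 12 were marked as having too much data. A value of exactly 0 can be a failed estimate. The glycolytic gene tdh1, listed at 0 in both groups, was marked as having too much data. It does not show whether a 0 with status OK can be one too. Genes with a value of exactly 0 are described as listed at 0, with no fold.

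The 25 gene lists were fixed before the data were examined. A list's median difference was set against the medians of 10000 random lists of the same size, drawn from tested protein-coding genes in 20 bins of mean expression. A list stood apart when its median lay outside the central 95% of these. This replaced camera and was chosen after seeing the data. It describes these pooled values and is not a test. Among 25 lists, 1.25 would lie outside by chance. Lists of 30 genes were also drawn from simulated differences of 5011 genes with a trend on expression. Of 200 unshifted lists, 2% were called higher and 1.5% lower, and 97% of lists shifted by 1 on the log2 scale were called higher. The 1.25 and the rates for unshifted lists take genes to vary independently. Members of a real list can vary together, so these figures may be too low here. Counts per list adjusted over the list alone used the authors' p-values with Benjamini-Hochberg adjustment.

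The genes named were atf1 and pcr1, the 12 called genes with the largest log2 difference in each direction (8 in the lower direction) with at least 1 FPKM in a group, and from each list the members with the smallest p-value (4 where the list stood apart, otherwise up to 2). Other genes were chosen after their values were seen, and are said to be. Near-identical copies were searched with BLAST+ 2.17.0 in the gene sequences of the later assembly ASM294v3, at 95% identity over 50% of a gene. Of 7092 genes, 6746 had a sequence there and 244 had a copy. Coordinates are those of the authors' deposited table (ASM294v2). They give Cuffdiff's locus, which can hold several genes, and values of genes in such a locus are uncertain. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 10, median-of-ratios scaling, quantile normalization and a 2-fold minimum. Others, added after seeing the data, changed the background of the random lists, the scaling and the genes counted.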

Results

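RNA of fission yeast labelled as lacking pcr1 was compared between cells labelled with an empty plasmid and cells labelled with an Atf1 plasmid. Atf1 is a stress-response transcription factor of the bZIP family, and Pcr1 is its usual dimer partner. The series asks how expression changes when Atf1 is over-expressed without pcr1. There were 2 libraries in each of the 2 groups, and the values are the authors' pooled FPKM, 1 per group and gene, so no spread between libraries can be given. FPKM summed to 1321550 in the Atf1-labelled group and to 835070 in the vector-labelled group. The median difference was -0.11 on the log2 scale over 6219 tested genes and -0.21 over 5011 protein-coding genes.

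The genes named in the genotype did not follow the labels. The level of atf1 (SPBC29B5.01, chromosome II 1545428-1549862) was 54.4 FPKM in the libraries labelled Atf1 and 60.9 FPKM in those labelled vector, and the authors' deposited table gives q = 0.997. The locus of atf1 holds 2 genes. The gene pcr1 (SPAC21E11.03c, chromosome I 4252142-4253622), deleted per the labels, was at 66.4 and 35.8 FPKM, with q = 0.774 in the authors' deposited table. It was therefore read in both groups, although which part of the gene was deleted is not given in the sources used here. The marker ura4 (SPCC330.05c, chromosome III 115589-116726), which the labels place at pcr1 in all libraries, was listed at 0 in the libraries labelled Atf1 and at 124.8 FPKM in those labelled vector. Every direction below is therefore between libraries labelled Atf1 and libraries labelled vector, and not between known levels of Atf1.

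Other genes were chosen after their values were seen. The mitotic inhibitor kinase wee1 (SPCC18B5.03, chromosome III 721788-725835) was at 282 FPKM with the Atf1 label and 5.75 FPKM with the vector label, a 49.0-fold difference that the authors' deposited table calls at q = 0.00809. The mating-type genes mat2-Pc and mat2-Pi, annotated in the silent P cassette, were listed at 0 with the Atf1 label and at 49.6 and 14.3 FPKM with the vector label. These values do not show whether the reads came from that cassette or from the same genes at the expressed mating-type locus. The authors' deposited table calls both at q = 0.00809. The plasmid promoter's own gene nmt1 was at 34770 FPKM with the Atf1 label and 12394 FPKM with the vector label, without a call, and ade6 was at 177 and 113 FPKM. The P-factor gene map2 was at 2.59 and 49.95 FPKM, and the receptor gene map3 at 1.59 and 7.41 FPKM, without a call. The M-factor genes mfm1 (222 and 195 FPKM) and mfm2 (314 and 290 FPKM) were close, while mfm3 was at 104 and 361 FPKM. The P-cell gene map4 was at 7.54 and 8.83 FPKM. The M-cell genes mam1, mam2 and sxa2 were at 21.7 and 10.7, 15.9 and 40.0, and 23.8 and 15.4 FPKM. The values of nmt1, map3, mfm3 and mam1 are uncertain, since their loci hold 5, 4, 4 and 8 genes, and those of map2, mam2 and sxa2 hold 2 each. None of these M-cell and P-cell genes other than those of the mat2 cassette was called.

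**Figure D1:**
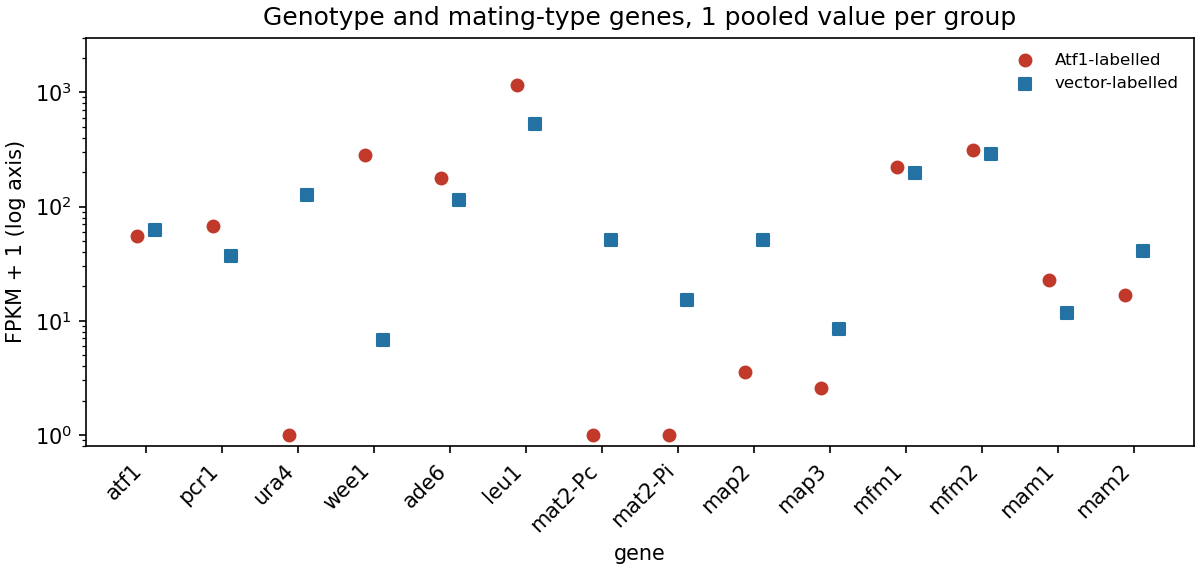
Authors' pooled FPKM + 1 (log axis) of genotype and mating-type genes, with circles for the Atf1-labelled and squares for the vector-labelled libraries, 1 value per group and so no error bars. Points at 1 are listed at 0 FPKM: ura4, mat2-Pc and mat2-Pi in the Atf1-labelled libraries. The levels of atf1 were 54.4 and 60.9 FPKM.

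The authors' deposited table calls 121 genes, of which 113 were higher and 8 lower in the libraries labelled Atf1. At an unadjusted p under 0.05 these were 431 and 255 genes. Among the called genes that were higher, 89 were protein-coding and 15 noncoding RNAs. The rest were structural RNAs: 3 rRNAs, 2 snoRNAs, 1 snRNA and 3 others. The gene SPAC4H3.08 (chromosome I 3841498-3843136) rose from 8.17 to 1734 FPKM, and lsd90 from 11.5 to 932 FPKM. The adenine-repressible gene rds1 rose from 23.1 to 2130 FPKM, and the glutathione peroxidase gene gpx1 from 50.7 to 2360 FPKM. Both lie in a locus of 3 genes. SPBC1289.14, pdc102, the hexose transporter gene ght7 and fub2 rose from under 1 FPKM to 110, 73.9, 62.3 and 63.1 FPKM. SPBPB21E7.11, SPAC977.18 and SPNCRNA.136 rose to 72.8, 322 and 94.2 FPKM, and the last 2 have a near-identical copy, so their values are uncertain. The genes fub2, SPBPB21E7.11, SPAC977.18 and SPNCRNA.136 each lie in a locus of 2 genes. These, pdc102 and ght7 lie within 100 kb of a chromosome end.

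Of the 8 genes lower with the Atf1 label, 5 were listed at 0 there: ura4, mat2-Pc, mat2-Pi and the noncoding RNAs SPNCRNA.504 (82.6 FPKM with the vector label) and SPNCRNA.99 (38.7 FPKM). SPNCRNA.504 shares a locus of 5 genes with nmt1 and gut2, which was at 164 FPKM with the Atf1 label and listed at 0 with the vector label, so its value is uncertain. The other 3 were SPAC869.05c, which fell from 41.0 to 7.54 FPKM, the small nucleolar ribonucleoprotein gene nop10, from 402 to 90.1 FPKM, and SPAC1B9.03c, from 42.3 to 9.81 FPKM. By value alone, 357 tested genes were at least 4-fold higher and 62 at least 4-fold lower. These counts include structural RNAs, most of which were higher with the Atf1 label. With median-of-ratios scaling these were 395 and 54 genes, and with quantile normalization 328 and 68. When both groups were scaled to equal FPKM totals, a choice made after seeing the data, they were 231 and 252. Of the scalings tried, only that one ended the excess of higher genes, so the balance depends on the scaling.

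**Figure D2:**
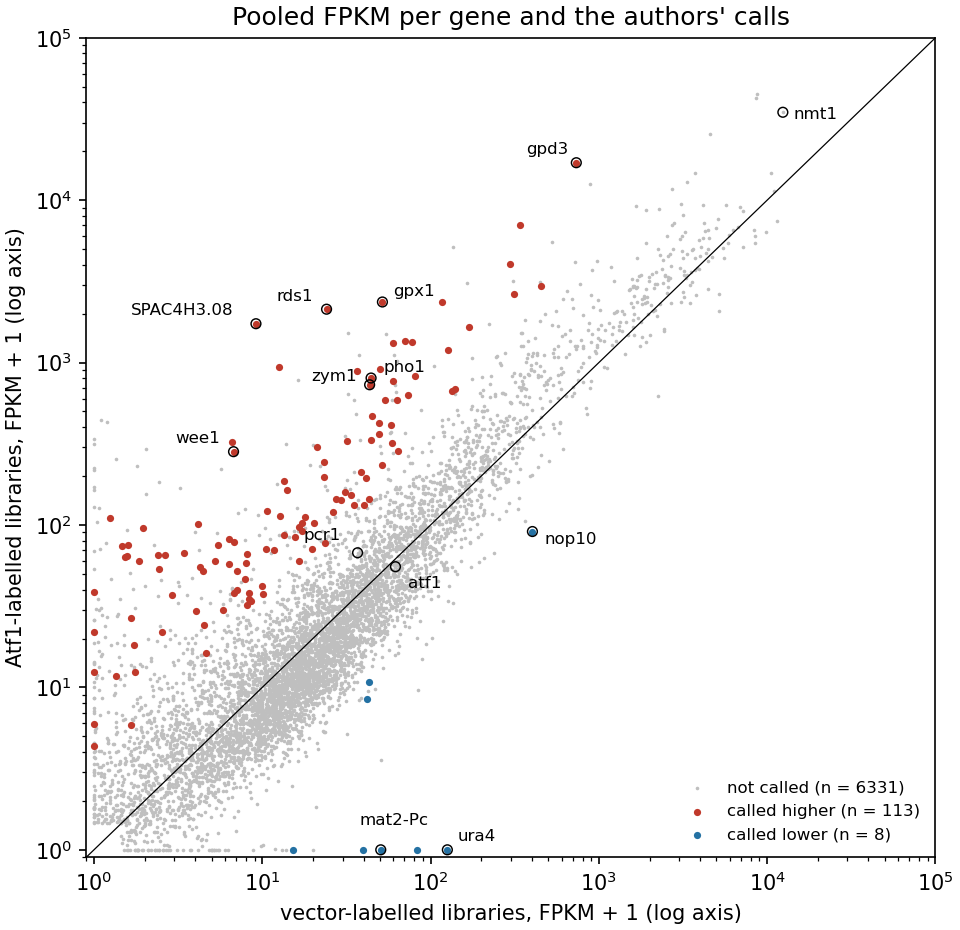
Authors' pooled FPKM + 1 of each gene with status OK in the vector-labelled (x axis) and Atf1-labelled (y axis) libraries, both axes logarithmic, with the line of equal values. Red and blue points are the 113 genes called higher and the 8 called lower in the authors' deposited table, and named genes are circled.

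The induced core environmental stress list stood higher with the Atf1 label, while heat shock and oxidative stress genes lay inside the random range. The core list had a median difference of 1.04 over 29 tested members, against 0.30 in random lists of matched expression (percentile 99.97), and 27 members were above 0. The authors' deposited table calls 4 of them, all higher, and 6 are past the threshold adjusted over the list alone. The metallothionein gene zym1 rose 17.2-fold, the catalase gene ctt1 10.7-fold and the glycerol-3-phosphate dehydrogenase gene gpd1 13.7-fold. The stress-activated MAPK list had a median of 0.07 against -0.30 (percentile 97.69), with 1 of 28 members called, the RNA-binding protein gene csx1 (3.38-fold). That list no longer stood apart under 5 alternatives, including matching on coding length. The oxidative stress and Pap1 list lay inside the random range (percentile 53.01), with 3 of 29 members called higher and 5 adjusted over the list alone. Heat shock genes lay inside it as well (percentile 18.64), with 0 of 27 called. Structural RNAs without poly(A) tails were also higher in the libraries labelled Atf1, at a median difference of 3.37 over 70 RNAs, a measured difference that stands beside every group described here.

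Glucose-repressed and hexose transport genes had a median of 1.496 over 30 members, against 0.20 in random lists (percentile 100). The authors' deposited table calls 4 higher, and 10 pass adjusted over the list alone. The called members include ght7 (0.53 to 62.3 FPKM) and the hexose transporter gene ght3 (14.6 to 83.2 FPKM). Both lie within 100 kb of a chromosome end. The others called were gpd1, also in the core stress list, and tgp1, also in the phosphate list. Iron uptake genes had a median of 0.41 against -0.03 (percentile 98.77), with 5 of 26 called, all higher, and 6 adjusted over the list alone. The ferric reductase gene frp1 rose 16.7-fold, sib2 11.0-fold, the iron permease gene fip1 10.6-fold and str3 9.53-fold, where sib2 lies in a locus of 4 genes. The list no longer stood apart without members within 100 kb of a chromosome end, or against random lists of all tested genes. Phosphate-responsive genes had a median of 1.11 against -0.05 over 6 members (percentile 99.57), with 2 called, the acid phosphatase gene pho1 (43.3 to 802 FPKM) and tgp1 (7.35 to 34.2 FPKM), and 3 adjusted over the list alone. Matching on GC content ended that list's standing. Its members pho1 and pho84 lie within 100 kb of a chromosome end, and without them the list was too small to compare.

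Flocculation and cell adhesion genes had a median of 0.59 over 19 members against -0.38 (percentile 100). The authors' deposited table calls 3, and 5 higher and 1 lower pass adjusted over the list alone. The adhesin genes pfl4, gsf2 and pfl3 rose 9.07-fold, 4.20-fold and 4.37-fold, where pfl4 and pfl3 lie in loci of 2 and 3 genes. Nitrogen starvation genes had a median of 0.45 over 26 members against -0.24 (percentile 99.97), with 3 called higher and 4 adjusted over the list alone. The peptide transporter gene isp4 rose 13.3-fold and car1 6.55-fold. Thiamine-repressed genes lay inside the random range (percentile 51.40), although pdc201 (18.9 to 70.4 FPKM) was called higher. The other member called was the same car1 gene counted under nitrogen starvation. It was matched by symbol as an alias of bsu1, so it may not be the thiamine gene meant.

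Mating and pheromone genes lay inside the random range (percentile 56.06), with 1 of 31 members called higher, ste7, and 1 lower, mat2-Pc. Over the list alone 2 were higher and 1 lower. Meiosis and sporulation genes also lay inside the random range (percentile 74.22), with 0 of 44 called, but they stood higher among genes with a mean of at least 10 FPKM.

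DNA damage checkpoint and repair genes stood lower than random lists, at -0.82 against -0.44 over 33 members (percentile 0.23), with 0 called. The excision endonuclease gene uve1 was at 6.12 FPKM with the Atf1 label and 18.2 FPKM with the vector label. The G2/M list lay inside the random range (percentile 10.16), and its called member was wee1. It stood lower when matched on GC content or set against all tested genes. G1/S genes (percentile 46.73), silencing factors (percentile 64.97) and septation genes (percentile 42.35) lay inside the random range, with 0 called. In the septation list 5 members were lower adjusted over the list alone, among them adg1 (14.0 and 87.9 FPKM) and adg2 (19.1 and 82.5 FPKM).

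Ribosome biogenesis genes had a median of -0.63 over 63 members against -0.24 in random lists (percentile 0.00), and 11 members were above 0. The authors' deposited table calls 1, nop10. Cytosolic ribosomal protein genes had a median of 0.35 against 0.55 (percentile 0.00) with 0 of 129 called. Matched on coding length as well, they no longer stood apart. Respiratory chain (percentile 52.08), amino acid (percentile 28.37), proteasome (percentile 6.34) and autophagy (percentile 82.27) genes lay inside the random range with 0 called. The proteasome list's median (-0.002) and mean (0.012) differ in sign, and it stood lower under quantile normalization. The sterol list lay inside it too (percentile 96.66), with erg24 called higher (42.1 to 143 FPKM), and stood higher with a pseudocount of 5. The Tf2 and wtf list stood higher (0.13 against -0.45, percentile 99.78) with 0 of 25 called. The tested members were all wtf genes, and 6 have a near-identical copy, so their values are uncertain. This list no longer stood apart under 4 alternatives, including no filter and matching on coding length.

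**Figure D3:**
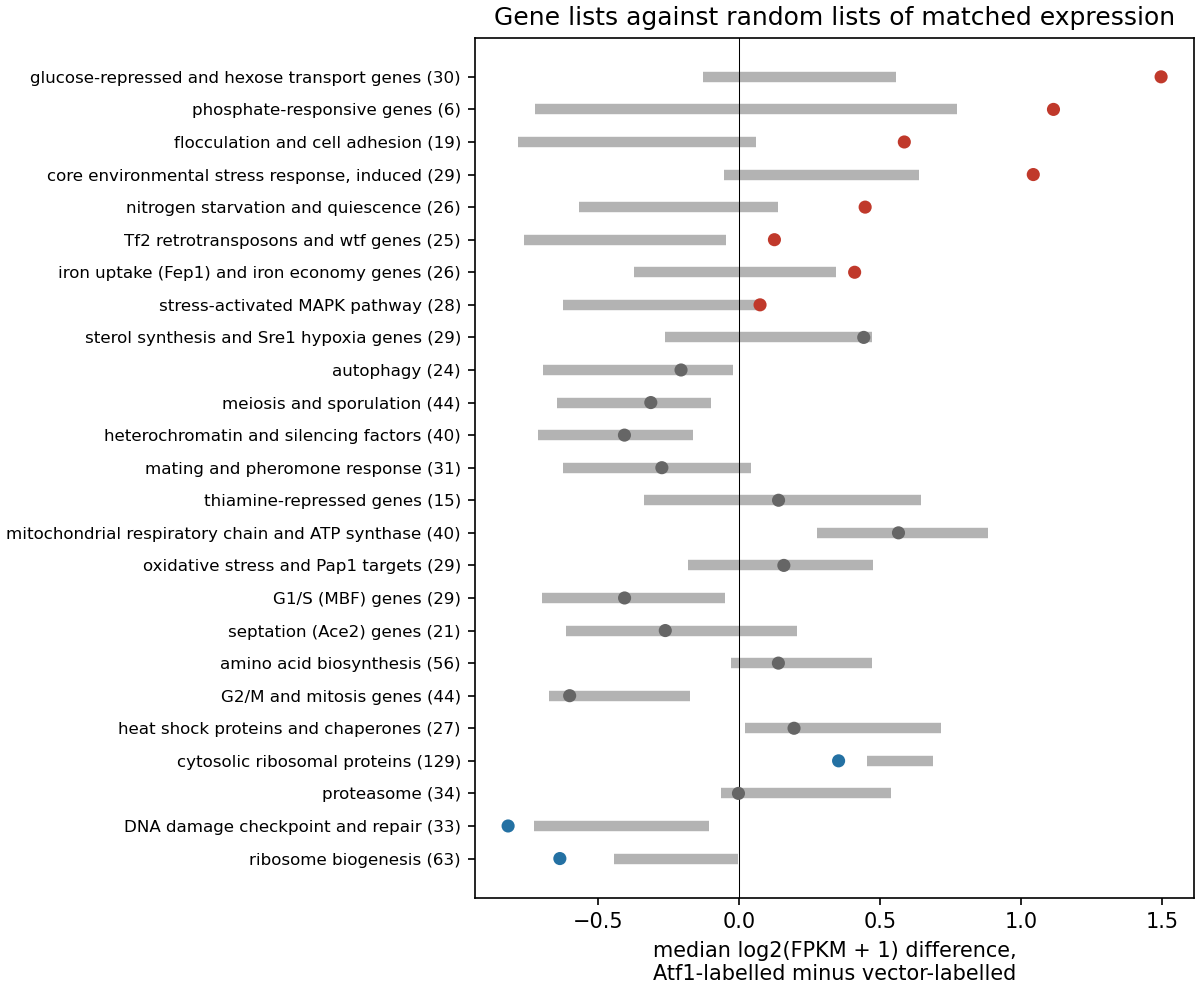
Median log2(FPKM + 1) difference of each of the 25 gene lists (points, Atf1-labelled minus vector-labelled), with the number of tested members in brackets and the central 95% of 10000 random lists of matched expression (grey bars). Red points lie above and blue points below the bars: 8 lists stood higher and 3 lower.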

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

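The tests on genotype genes and structural RNAs were chosen after the result was seen. Structural RNAs, which lack poly(A) tails, are outside the comparison of messenger RNAs, and their median difference was 3.37 on the log2 scale, with 66 of 70 above 0. They made up 3.36% of all FPKM with the Atf1 label and 1.24% with the vector label. A difference in scaling is argued against, because they stood 3.58 above protein-coding genes. Carry-over of such RNA in library preparation may be the source: the medians of the 4 classes with at least 5 RNAs ran from 2.91 to 4.10. It cannot be told apart from a change in these RNAs, since it is confounded with the group. An effect of Atf1 over-expression was not tested on them, and atf1 RNA itself was not higher (54.4 against 60.9 FPKM).

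The genotype genes went against the labels. Scaling between the groups is argued against for atf1, since 51.9% of tested genes lay above it, and so are exchanged group names, since 48.1% lay below it. A failed estimate stays open for ura4: of other protein-coding genes with status OK and alone in their locus, 0 of 715 with at least 50 FPKM in a group were listed at 0 in the other, but 4 of 1525 with at least 10 FPKM were. These are mat2-Pc and mat2-Pi, of the same pattern, and SPBC1348.08c and SPBCPT2R1.05c, which have a near-identical copy and are at 0 with the vector label. The gene eno101, listed at 0 against 4695 FPKM, was marked as having too much data, so it says little of genes with status OK. Such zeros in 1 group were rare among genes with status OK and alone in their locus. That rarity cannot decide a single failed estimate at ura4. Another strain than labelled stays open too. The libraries labelled Atf1 met 0 of 4 label features, but these are the genes the pattern was seen in, so the score decides nothing. RNA of pcr1 was read in both groups. For wee1, a change of the whole region is argued against by a median of -0.42 over 12 neighbours within 15 kb, and what raised it was not tested.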

How the results depend on the processing

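No paired analysis was possible because the files hold 1 pooled value per group. For the same reason leaving out libraries, limma, camera and fry were not run, and DESeq2 needs counts. The counts of 113 and 8 called genes were the same with a 2-fold minimum, and 105 and 7 with a mean of at least 10. All other alternatives for called genes, the 4-fold counts, equal totals, and the other backgrounds and the chromosome-end alternative for lists were chosen after seeing the data. Called genes were 72 and 3 at q under 0.01, fewer by the stricter threshold, and 3 lower genes had no value listed at 0. Adjusted over this table's genes they were 137 and 12. Genes at least 4-fold lower (62) were 129 with a pseudocount of 0.1, 13 with 5, and 28 with a mean of at least 10. With equal totals, 231 were at least 4-fold higher and 252 lower. That scaling moved the median of tested genes by -0.61, and median-of-ratios scaling by 0.11. The difference of atf1 (-0.16) was -0.15 with a pseudocount of 5, -0.041 with median-of-ratios scaling, -0.34 with quantile normalization and -0.81 with equal totals. That of pcr1 (0.87) was 0.89 and 0.81 with pseudocounts of 0.1 and 5, then 0.99, 0.77 and 0.22 under those scalings. Apart from fewer genes at stricter limits, the cause was not tested. The 11 lists standing apart were 8 to 12 under the 12 alternatives, and none of these 11 turned direction, while 9 of the other lists changed sign under an alternative. Single lists lost their standing in 13 cases and gained it in 5. Unknown depth limits what can be said of genes with low FPKM.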

Other observations

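The tests on chromosome ends were written before their results were seen, but after the pattern itself was, and the comparison per chromosome was chosen later. Gene Ontology terms were compared after seeing the data. Of 379 terms with at least 8 tested genes, 20 stood above and 42 below random lists of matched expression. By chance 18.95 would lie outside if genes varied independently, which members of a term may not. Flocculation had the highest median difference, 3.27 over 8 genes, against -0.29 in random lists, with 3 called higher. Canonical glycolysis had a median difference of 2.18 over 11 genes, against 0.55 in random lists. The glyceraldehyde-3-phosphate dehydrogenase gene gpd3 was at 17004 FPKM with the Atf1 label and 733.5 FPKM with the vector label. It was the only member of the glycolysis term called in the authors' deposited table. The levels of gpm1 were 45035 and 8661 FPKM, and those of pgk1 25652 and 4550 FPKM. The loci of gpd3 and gpm1 hold 4 and 3 genes, so their values are uncertain. Differences rose with mean expression across tested protein-coding genes (Spearman 0.35), so 20 bins may not fully match genes this abundant. Outside the tested genes, eno101 was listed at 0 with the Atf1 label and at 4695 FPKM with the vector label, and tdh1 at 0 in both. The tricarboxylic acid cycle had a median of 1.04 over 18 genes, against 0.44.

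On the lower side, rRNA processing had a median of -0.84 over 111 genes, against -0.27 in random lists, and tRNA methylation -1.04 over 19 genes, against -0.40. The 102 genes of mitochondrial translation had a median of -0.56 against -0.24. None of the members of these 3 terms was called in the authors' deposited table.

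Protein-coding genes within 100 kb of a chromosome end had a median difference of 1.56 in favour of the Atf1 label, over 174 of 5011 tested genes. Of the 113 genes of all kinds called higher, 32 lay there. The medians were 2.18 on chromosome I, 2.64 on chromosome II and 0.02 on chromosome III. An end is here the start of the coordinates or the last gene listed. On chromosome III that gene is the rRNA gene SPRRNA.45, so its ends may not be like those of the other chromosomes. On chromosome III this lay at percentile 97.94 of matched random lists, and on the other chromosomes at percentile 100. Within 25 kb the medians were 1.64, 1.56 and 1.36 on chromosomes I, II and III, the last over 4 genes. Whether the chromosomes differ was not tested. Expression level is argued against, since the highest of 10000 matched random lists had a median of 0.08. Near-identical copies are argued against as the whole cause. The median was 1.26 over 131 genes once those with a copy, or with no sequence in the reference to search, were left out. Without members of the fixed lists it was 1.55 over 153 genes, so those members are argued against as the whole cause. This says little of other stress, nutrient or adhesion genes, since most genes near the ends are in none of these lists. A difference in strain was not tested on these genes, nor was an effect of Atf1 over-expression, and atf1 RNA was not higher (54.4 against 60.9 FPKM).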
